A study of Trichoderma reesei with 2 samples.

How the data were processed

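Gene expression was measured by RNA sequencing in hyphae of strain HJ48 of Trichoderma reesei, a filamentous fungus best known for secreting cellulases, at an age of 4 days during ethanol fermentation. Total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit for Illumina from 3 micrograms of RNA, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1, without a role or an order. The genome build, the annotation, the strandedness of the counting and any filter are not given in the sources used here.

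The 2 libraries carry contradictory labels. The library whose title and source name say anaerobic has a condition field that says aerobic, and the library titled aerobic has a condition field that says anaerobic. The libraries were therefore grouped by title and are called the library titled anaerobic and the library titled aerobic throughout. Each column of the table was matched to its sample through the sample's description. If the condition fields rather than the titles are correct, every direction between the conditions is the opposite of the one the titles give. The series' design text speaks of 3 replicates per condition, but the table holds 1 column per condition, and the sources used here do not say whether a column is 1 culture or a pool.

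The authors deposited 1 FPKM value (fragments per kilobase of gene model, scaled to library size) per gene model and library, for 9129 gene models. Per the file headers, genes are named only by gene model identifiers, with no symbol or product. None of these identifiers (0 of 9129) was found in the table of 9116 RefSeq genes of strain QM6a that was available. The 24 gene lists written before the data were examined (among them cellulases, hemicellulases, glycolysis, the ethanol branch, the respiratory chain and conidiation genes) had no matched member, so no list was analysed and no gene is named by function. For this case the naming rule, also fixed beforehand, allowed 2 identifiers per direction: the 2 gene models with the highest and the 2 with the lowest log2 ratio among those at 10 FPKM or more in either library. Scaffold numbers are those written in the model names. Chromosome positions are not given, because no annotation of these models was used here.

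The depth behind the FPKM values was recovered from the values. The ratio of the deposited FPKM columns over low gene models took whole-number ratios times 1 constant, 1.09358, and 49 low gene models sat at that constant itself. Divisors between 1000000 and 40000000 were searched for those that turn the FPKM of 200 low gene models into whole reads over whole lengths. The chosen divisors, 8887469 for the library titled anaerobic and 8126938 for the library titled aerobic, gave a whole length for 80.5% of them. The other solution, at 26662407 and 24380814, gave 70.5% and let the reads add up to only 54.5% and 56.4% of the divisors. At the chosen divisors, the smallest whole reads and length (30 to 40000 bp) were found for all 8910 gene models with a value above 0. These reads add up to 90.9% of the divisor in the library titled anaerobic and 91.0% in the library titled aerobic. Reads that share a factor with the length come out too small, which widens their intervals. The recovered lengths had a median of 1099.5 bp and were multiples of 3 in 90.6% of models without an estExt or kg2 prefix, against 42.4% of models with the estExt prefix. Tested on a simulated table of 9129 gene models, the procedure returned 2 of 2 divisors exactly, and the true reads and length, or these over a common factor, in 99.9% of gene models. The exact reads were returned in 79.4%.

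Log2 ratios were computed as titled anaerobic over titled aerobic on the log2(FPKM + 1) scale, which understates the change of low gene models. Gene models at 1 FPKM or more in either library were compared, and a difference of at least 2-fold on that scale was counted. With 1 library per group there is no replicate check, so no p-value is given for a difference of a gene model between the conditions. The Poisson p-values given at the end set read numbers of these 2 libraries against a carry-over rate and do not test the conditions. For each ratio a 95% exact (Clopper-Pearson) interval was computed from the recovered reads. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The limit that a count of 0 allows, 3 reads, corresponds to 0.307 FPKM in the library titled anaerobic and 0.336 FPKM in the library titled aerobic for a gene model of median length. On simulated reads of 8197 gene models, the 2-fold rule found 100 of 100 gene models raised 4-fold and 92 of 100 lowered 4-fold, and called 62 of 7997 unchanged ones. In that simulation 95.6% of the intervals held the true ratio. The simulated reads held Poisson counting error only, with no variation between cultures and no shift common to all gene models. The simulation therefore does not give the rate of false calls in the data.

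Alternatives set before the data were examined were pseudocounts of 0.1 and 5, equal sums, a median-centred scaling, a trimmed mean of ratios (TMM, trimming 30% of ratios and 5% of abundances at each end, unweighted), no filter, a filter at 10 FPKM, leaving out the 20 highest gene models, and a 4-fold threshold. Replicates could not be left out or blocked, since each group holds 1 library. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.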

Results

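The series set out to compare the transcriptome of T. reesei HJ48 during ethanol fermentation without and with oxygen. It consists of 2 RNA libraries from 4-day-old hyphae, 1 titled anaerobic and 1 titled aerobic. The condition field of each library contradicts its title, so directions below are between the titled libraries and are not assigned to oxygen supply. The per-million values were scaled to 8887469 reads or fragments in the library titled anaerobic and 8126938 in the library titled aerobic. Each group holds 1 library, so differences have no replicate check, and intervals cover counting error only.

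The distribution of transcript levels differed in shape between the libraries. In the library titled aerobic, most gene models formed a broad peak, with a median of 22.5 FPKM and quartiles of 4.997 and 62.1 FPKM. In the library titled anaerobic, the median was 3.62 FPKM, with quartiles of 0.651 and 18.6 FPKM, and no such peak was present. At 1 FPKM or more, 6360 of 9129 gene models were detected in the library titled anaerobic and 7919 in the library titled aerobic. At 10 FPKM or more the numbers were 3083 and 5983. The order was the other way round for the most abundant transcripts, as 139 gene models reached 1000 FPKM in the library titled anaerobic and 104 in the library titled aerobic. All these counts use FPKM as deposited and were not repeated with another scaling, which would change them. The 100 most abundant gene models held 62.3% of the summed FPKM in the library titled anaerobic and 45.5% in the library titled aerobic, and the top 10 held 29.3% and 24.8%.

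**Figure D1:**
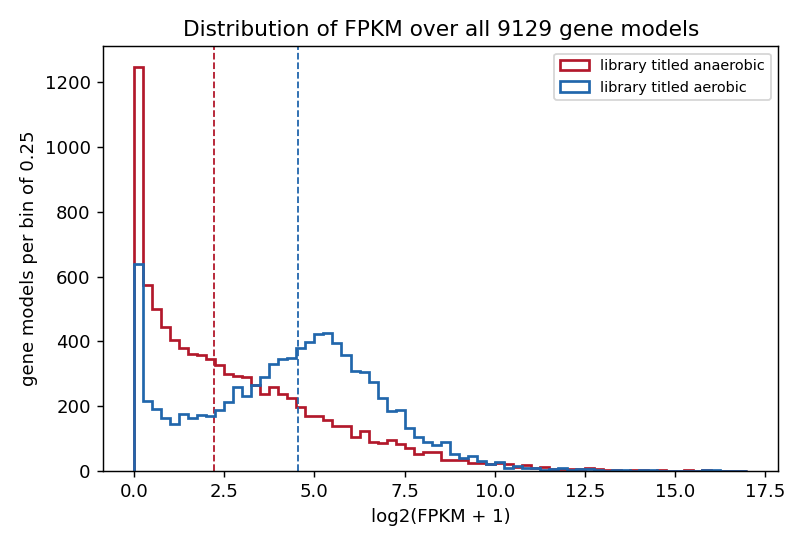
Number of gene models (vertical axis) per bin of log2(FPKM + 1) (horizontal axis) for all 9129 gene models in the library titled anaerobic (red) and the library titled aerobic (blue); dashed lines mark the medians of 3.62 and 22.5 FPKM. The blue curve has a peak of expressed gene models to the right of its zero bin, whereas the red curve falls steadily.

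Most gene models were lower in the library titled anaerobic. Of 8197 gene models at 1 FPKM or more in either library, 5411 (66.0%) were at least 2-fold lower there, 1064 (12.98%) were at least 2-fold higher, and 1722 (21.0%) lay within 2-fold. The median log2 ratio of titled anaerobic over titled aerobic was -1.85, with a 95% interval over gene models of -1.90 to -1.79 that treats gene models as independent. Differences of at least 4-fold were seen for 3868 lower and 565 higher gene models. Counting error alone accounted for few of these: the interval of the ratio excluded equality for 5335 of the 5411 lower and 1027 of the 1064 higher gene models. The balance of directions depended on the scaling. Higher gene models made up 16.4% of the 2-fold differences with FPKM as deposited and 50.2% after TMM scaling, which raised every ratio of FPKM values by 2.16 on the log2 scale and gave 2494 higher and 2476 lower gene models. Across gene models, which are not independent replicates, log2 levels in the 2 libraries correlated with a Pearson r of 0.52 and a Spearman rho of 0.51.

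**Figure D2:**
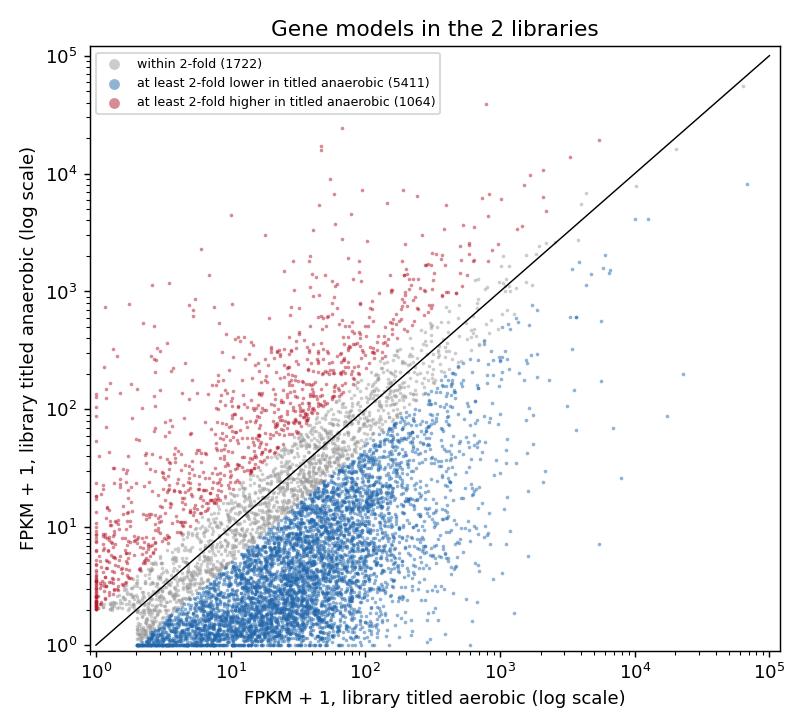
FPKM + 1 of each gene model in the library titled aerobic (horizontal axis, log scale) and the library titled anaerobic (vertical axis, log scale), 1 point per gene model at 1 FPKM or more in either library; the line marks equality. The 5411 blue points at least 2-fold lower in the library titled anaerobic form a dense cloud at low and middle levels, and the 1064 red points extend to the highest levels.

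The share of gene models higher in the library titled anaerobic was larger in the upper abundance groups. The groups were cut on the mean of the 2 FPKM values as deposited, also where another scaling is given. That mean follows the larger of the values that form the ratio, so the grouping and the ratio are not independent. Among 2670 gene models with a mean under 10 FPKM, 65.2% were at least 2-fold lower in the library titled anaerobic and 10.4% were higher, with a median log2 ratio of -1.54. Among 4337 gene models with a mean of 10 to 100 FPKM over both libraries, 71.6% were at least 2-fold lower in the library titled anaerobic and 9.94% were higher, with a median log2 ratio of -2.40. Among 1076 gene models with a mean of 100 to 1000 FPKM, 49.3% were lower and 27.8% higher. Among the 114 gene models with a mean of 1000 FPKM or more, 33 were lower and 57 higher, and the median log2 ratio was 1.03. The direction within a group depends on the scaling, which moves all ratios alike. With the scaling on gene models at 10 FPKM or more in both libraries, the group with a mean of 100 to 1000 FPKM had 35.4% higher and 40.4% lower. With TMM scaling, which moves ratios further, it had 52.4% higher and 26.2% lower, the group under 10 FPKM had 610 higher and 537 lower, and the group with a mean of 10 to 100 FPKM had 1237 higher and 1642 lower.

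The most abundant transcripts were in large part different ones. The 100 most abundant gene models of the 2 libraries shared 33 members, where independent lists would share 1.10. The gene models counted next were chosen by a high value in 1 library, which by itself favours a higher value in that library. Of the 139 gene models at 1000 FPKM or more in the library titled anaerobic, 100 were at least 2-fold higher there, 28 lay within 2-fold and 11 were at least 2-fold lower there. Among them, 13 were at least 100-fold higher. Of the 104 gene models at 1000 FPKM or more in the library titled aerobic, 68 were at least 2-fold higher there, 26 lay within 2-fold and 10 were at least 2-fold lower there. That direction depends on the scaling: 55 were higher in the library titled aerobic and 17 lower there with the scaling on gene models at 10 FPKM or more in both. The numbers were 33 and 41 with TMM scaling. They were 35 and 35 with a scaling by the median log2 ratio of all compared gene models, which left a median of -0.33. The most abundant gene model of the library titled anaerobic was similarly abundant in both, at 55275 FPKM there and 64097 FPKM in the library titled aerobic. The next stood at 44744 and 121 FPKM. The most abundant gene model of the library titled aerobic had 68674 FPKM there and 8132 FPKM in the library titled anaerobic.

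Some gene models were close to absent in 1 library. Of these, 13 were at 100 FPKM or more in the library titled anaerobic and under 1 FPKM in the library titled aerobic, and 53 showed the opposite. At 10 FPKM or more in the library titled anaerobic, 10 gene models were listed at 0 in the library titled aerobic, against 75 in the other direction. These numbers use FPKM as deposited. They were not recounted with another scaling, which would move the thresholds of 1 library against the other. The gene model with the highest log2 ratio, 9.32, was fgenesh5_pg.C_scaffold_26000081 on scaffold 26. It had 741 FPKM in the library titled anaerobic and 0.162 FPKM in the library titled aerobic, from 5000 reads against 1 read over 759 bp. That is a 4572-fold difference with a counting interval of 820 to 180625. The next was fgenesh5_pg.C_scaffold_27000036 on scaffold 27, with 789 FPKM in the library titled anaerobic and 0.746 FPKM in the other, a 1058-fold difference (interval 189.5 to 41824) that rests on 1 read in the library titled aerobic. In the opposite direction, e_gw1.15.374.1 on scaffold 15 had 5440 FPKM in the library titled aerobic and 6.25 FPKM in the library titled anaerobic. Its level was 870-fold higher in the library titled aerobic, with an interval of 557 to 1446 from 15119 and 19 reads. The gene model e_gw1.12.318.1 on scaffold 12 had 1258 FPKM in the library titled aerobic and 0.872 FPKM, or 1 read, in the library titled anaerobic, a 1442-fold difference with an interval of 258 to 57016. The deposited table gives no function for these 4 gene models.

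Gene models that were higher in the library titled anaerobic were unevenly spread over the scaffolds. On scaffold 7, 106 of 403 gene models (26.3%, 95% exact interval 22.1 to 30.9) were at least 2-fold higher in the library titled anaerobic, against 12.98% of all 8197. On scaffold 17, 8 of 199 were higher (4.02%, interval 1.75 to 7.77). The median log2 ratio was -0.93 on scaffold 7 (interval -1.19 to -0.64) and -2.06 on scaffold 17 (interval -2.49 to -1.78). The interval of scaffold 17 holds the median of all compared gene models, -1.85. By median, the lowest was scaffold 25, at -2.60 (interval -3.06 to -2.23). Scaffold 7 had the highest and scaffold 17 the lowest share among 28 scaffolds with 100 or more such gene models. TMM scaling moves all ratios alike and so could hardly remove a difference between scaffolds. With it, 46.7% were higher on scaffold 7, 19.1% on scaffold 17 and 30.4% of all gene models. The median log2 ratio of scaffold 7 then turned to 0.90. The intervals treat neighbouring gene models as independent, and these scaffolds were singled out after their values were seen.

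**Figure D3:**
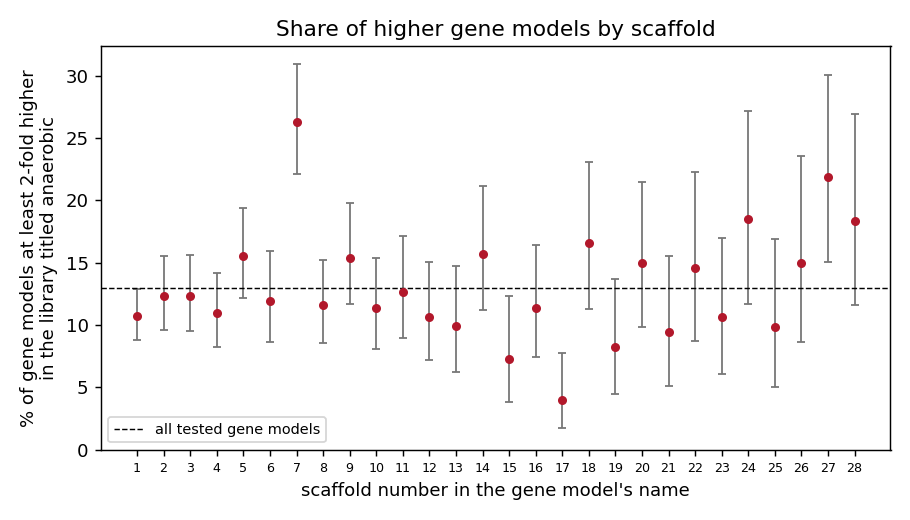
Share of gene models at least 2-fold higher in the library titled anaerobic (vertical axis, percent) for each of 28 scaffolds with 100 or more gene models (horizontal axis, scaffold number); bars are 95% exact binomial intervals and the dashed line is the share of all 8197 gene models, 12.98%. Scaffold 7 stands highest at 26.3% and scaffold 17 lowest at 4.02%.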

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

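The counts of lower gene models (4372 to 5577) and of higher ones (829 to 1487) stayed within 1.5 times the reported 5411 and 1064 under the other pseudocounts, equal sums, the scaling on gene models at 10 FPKM or more in both, both filters and leaving out the 20 or 100 highest gene models. TMM scaling, which removes a common shift by construction, changed the counts to 2494 higher and 2476 lower. Scaling by the median log2 ratio of all compared gene models gave 2220 higher and 2895 lower. That shift was computed with the pseudocount, which was added again after scaling. It therefore removed the common shift only in part, and a median log2 ratio of -0.33 over all 8197 gene models remained. A 4-fold threshold left 565 higher. The counting interval of the plain FPKM ratio lay wholly beyond 2-fold for 905 higher and 4974 lower gene models. These were counted over all 8197 gene models and are not a subset of the 2-fold differences. The 3 settings chosen after seeing the data were the count by interval, the scaling by the median of all compared gene models and leaving out the 100 highest. The median log2 ratio, -1.85 as reported, was -2.27 and -1.21 with pseudocounts of 0.1 and 5, -1.75 with equal sums, -1.26 with the scaling on gene models at 10 FPKM or more in both, and -0.034 with TMM, where nothing of its sign can be read. It was -1.56 without a filter, -2.25 with a filter at 10 FPKM, and -1.64 and -1.39 without the 20 and the 100 highest gene models. At a detection limit of 10 FPKM the library titled anaerobic held 3083 gene models. Of 31 values of the 4 named gene models under alternatives, 3 lay outside the counting interval of the plain ratio when it is placed about the reported value, all of them of e_gw1.15.374.1, such as -7.39 under TMM against -9.55. The sign stayed the same in all 31. It could hardly change, since these gene models were chosen for the most extreme ratios. No paired analysis was possible because each group holds 1 library, and no replicate could be left out. The alternatives for the fixed gene lists were not run, because no list had a matched member.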

Other observations

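All tests in this part were chosen after the data were seen. Gene models of different kinds differed in the share that was higher in the library titled anaerobic. Of 3208 gene models with the estExt prefix, 10.8% were at least 2-fold higher there (95% exact interval 9.73 to 11.9), against 17.8% of 1822 unextended fgenesh5_pg models (16.1 to 19.7). The other 3167 unextended models stood at 12.4% (11.3 to 13.6), among them fgenesh1_pm models at 9.98% and the 92 kg2 models at 21.7%. Extended fgenesh5_pg models stood at 10.9% (9.15 to 12.8) and extended fgenesh1_pm models at 10.3%, so the share differed with extension among fgenesh5_pg models, which was not seen among fgenesh1_pm models. After TMM scaling the shares were 28.9% for estExt models, 35.5% for unextended fgenesh5_pg models and 29.0% for the others. The unextended fgenesh5_pg models were also less abundant, with a median of 12.4 FPKM in the library titled aerobic against 46.0 FPKM for the estExt models and 22.5 FPKM for the others.

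The first pattern is the lower level of most gene models in the library titled anaerobic, in FPKM as deposited. It depends on the scaling: with TMM, which removes a common shift by construction, the median log2 ratio was -0.034. The summed FPKM were alike, 875530 in the library titled anaerobic and 971295 in the library titled aerobic. Lower values of most gene models thus go together with a larger share held by others. FPKM values are relative to library size, so they cannot tell a fall of most transcripts from a rise of the others. Leaving out a set wider than 100 gene models was not tested. A few dominant transcripts were weighed first: with the 100 highest gene models left out and the rest rescaled, the median log2 ratio was still -1.39 of the -1.85 reported, which argues against them as the whole cause. A loss of long transcripts is argued against by 8 bins of recovered length, of which the one nearest 0 had a median of -1.71. An even background, such as genomic DNA in the library titled aerobic, would have to bring about 22.8 FPKM to every gene model, yet 1210 gene models were under 1 FPKM there. A difference in RNA quality between the cultures, other batch effects and the oxygen supply that the design names may each play a part, and with 1 library per group these cannot be separated.

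The second pattern is a common ratio among abundant transcripts. Of 10 gene models at 10000 FPKM or more in the library titled anaerobic, 4 were over 100-fold higher there, and their folds lay between 345 and 371, with overlapping counting intervals (the widest limits being 312 and 403). A candidate explanation is reads of the library titled anaerobic carried over into the other library at that ratio, 0.249 reads per 100. Of 234 other gene models with 5000 or more reads in the library titled anaerobic, the most extreme had 1 read in the library titled aerobic against 12.5 that such carry-over alone would bring (exact Poisson test, one-sided p = 0.012 after Bonferroni adjustment over the 234). That gene model is fgenesh5_pg.C_scaffold_26000081, which already stood out by the highest ratio and lies exactly at the minimum of 5000 reads, a limit set after the data were seen. The next lowest adjusted p was 0.827. Among other gene models that fell short of the expected reads by the unadjusted test, 2 had 15 reads against 28.9 and 71 against 93.8. The evidence against carry-over at the full ratio thus rests on 1 gene model, so carry-over and a shared regulation of these transcripts, which was not tested, cannot be told apart.

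The third pattern is that neighbouring gene models had like ratios, on the assumption that the number in a model's name follows its order on the scaffold. Extended and unextended fgenesh5_pg models were kept apart, because 190 scaffold and number combinations occur in both, where unrelated numberings would give 261. Among unextended fgenesh5_pg models, log2 ratios correlated with r = 0.48 over 377 adjacent combinations (Spearman 0.42), 0.20 at a distance of 2 to 3 and 0.089 at 4 to 10 models (one-sided permutation within scaffolds, adjusted p = 3e-05, 3e-05 and 0.002 over 9 comparisons; 1e-05 is the smallest raw p that 100000 shuffles can give). The fgenesh1_pm models gave 0.77 over 32 adjacent combinations, 0.42 at a distance of 2 to 3 and 0.12 at 4 to 10 models (adjusted permutation p = 3e-05, 0.002 and 0.124), or 0.53, 0.36 and 0.0008 without abundance and scaffold trends. The e_gw1 models gave 0.038, 0.056 and 0.054 (adjusted permutation p = 0.465, 0.363 and 0.212), and whether their numbers follow position was not established. For unextended fgenesh5_pg models, the correlation at a distance of 2 to 3 was 0.17 with abundance and scaffold trends removed. Shuffles of the same trend-free values gave an upper limit of 0.068. This cannot exclude reads shared between adjacent models, since models at a distance of 2 may each share reads with the one between. The abundance and scaffold trends are argued against as the whole source by the 0.45 that adjacent models kept without them. At 4 to 10 models the correlation without these trends was small, 0.051, against an upper limit of 0.034 from such shuffles that is not adjusted for the number of comparisons. Shared reads may remain as an explanation. Tandem copies and domain-wise regulation may remain too and were not tested, since sequences and positions were not used here.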
